A study of Mus musculus with 38 samples.

How the data were processed

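The sources used here describe mouse CD8+ T cells that were sorted, combined into pools, 2 or 3 of which were biological replicates, with 5000 to 50000 cells each, and sequenced as read pairs of 50 bp. According to the submitters' notes, reads were aligned to mm10 with Bowtie2 2.2.9, and Picard 2.8.0, SAMtools 1.3.1, MACS2 2.1.1 and DESeq2 1.28.1 were used. How reads were shifted, how peaks were merged and how libraries were pooled is not given in the sources used here. Whether a library listed for a group is a biological or a technical replicate is not given either, and sequencing batches 4 and 5 share 1 entry, as do batches 1 and 2 for all endogenous libraries.

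As deposited by the authors, the tables held signal values per peak, which are reads in peaks divided by a size factor per library, made with DESeq2 according to their notes, 73610 peaks by 17 libraries and 169323 peaks by 21 libraries. Every column was used. Whole reads were recovered from each column and served for depth and for the count tests. Median peak width was 909 bp in the endogenous table and 513 bp in the other.

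Peaks with a mean of 10 or more over all libraries of a table were tested, 71756 and 84091. Log2 of normalized reads plus a pseudocount of 1 was fitted with limma 3.58.1 in R 4.3.3, with all groups of a table in 1 model, an intensity trend in the variance and, in the second table, a term for batch 6. Adjusted p-values are Benjamini-Hochberg values of limma unless another tool is named. The 13 comparisons were fixed before the data were examined, as were the gene lists and the alternatives. Alternatives were other pseudocounts, no filter, a mean of 30 or more, equal library totals, quantile scaling, array weights, a replicate block, a fit of the compared groups alone, edgeR 4.0.16, DESeq2 1.42.0, fits within a batch, a fit without the batch term and each library left out in turn. Python 3.11.15 and matplotlib 3.10.9 prepared tables and plots.

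Each peak was given to the nearest of 21883 protein-coding genes of the mm10 RefSeq annotation. The plan had been to use the nearest transcription start. The annotation used here gave gene starts and ends without strand, so the distance to the gene body was used instead, up to 100000 bp and in an alternative up to 10000 bp. A peak within 1000 bp of either end of a gene is called near a gene end, and others lie inside a gene or between genes. Most gene assignments of peaks between genes are therefore guesses from distance. A motif analysis had been planned and was not run, because no genome sequence was used here.

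Genes were named by rule: in each direction up to 8 called peaks of largest log2 difference, with library values that did not overlap and a mean of 30 or more in the higher group, then the 12 list genes of lowest adjusted p, and always Slamf6, Havcr2, Tcf7, Tox, Pdcd1, Gzmb and Gzmk at their lowest-p peak. The text uses a part of these. Levels are given in the order of the comparison.

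There were 15 gene lists, written from general knowledge: progenitor exhausted (19 genes), terminally exhausted (20), effector molecules and regulators (16), age-associated CD8 T cell genes (9), tissue residency (9), T cell receptor and costimulation (19), AP-1 family (11), interferon response (15), cell cycle (15), virtual memory (5), and lists of melanocyte and melanoma (7), myeloid (12), B cell (8), CD4 and regulatory T cell (7) and NK cell genes (6). Znf683 and Mx1 were not in the annotation used here. The set test was camera of limma with a preset correlation of 0.01, adjusted over the 15 lists, and again with the correlation estimated from the residuals. Genes with several peaks weigh more in it.

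The tests were tried on simulated reads with known changes, drawn from the means, dispersions and depths of the real peaks. At a fold of 2, limma recovered 38.8% of 67 changed peaks for endogenous Tterm age and 28.4% for Tprog age. OT-1 Tterm age gave 41.8% and naive age 2.99%. At a fold of 4 the shares were 72.7%, 78.8%, 86.4% and 36.4%. False calls made up 4.60% of 87, 9.52% of 84, 3.33% of 90 and 7.14% of 28 calls.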

Results

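The series holds ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, so that reads pile up where DNA is accessible. The cells were mouse CD8+ T cells from C57BL/6J animals aged 10-12 weeks (young) or 64-68 weeks (aged). Endogenous tumour-infiltrating cells came from B16-OVA melanoma at day 15 and were sorted into Tprog (Slamf6+ Tim-3-, progenitor exhausted), Tterm (Slamf6- Tim-3+, terminally exhausted) and, from aged animals, Tadys (Slamf6- Tim-3-, given in the labels as age-associated dysfunctional). OT-1 cells, which carry a transgenic receptor for ovalbumin, were sorted from the tumours as Tprog and Tterm, and naive cells came from spleen. The labels give an age for each OT-1 library and do not say which hosts those cells had been in.

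Depth is given as megareads in peaks per library. The endogenous table held 17 libraries and 73610 peaks: young Tprog (n = 4, 7.61 to 22.4), aged Tprog (n = 3, 4.64 to 27.8), young Tterm (n = 5, 9.93 to 87.6), aged Tterm (n = 3, 22.3 to 26.9) and Tadys (n = 2, 8.51 to 12.1). The other table held 21 libraries and 169323 peaks: young naive (n = 2, 12.9 to 15.9), aged naive (n = 2, 14.8 to 18.1), young OT-1 Tprog (n = 2, 9.30 to 9.71), aged OT-1 Tprog (n = 2, 6.80 to 13.5), young OT-1 Tterm (n = 7, 7.45 to 15.5) and aged OT-1 Tterm (n = 6, 8.29 to 27.7). The tables had been normalized apart, so every test stayed within 1 table. Groups and comparisons were written down before the data were examined. The unit in the text is normalized reads per peak, given as mean ± SD, and log2 differences carry ± SE. These differences come from the fit, whose batch term can set them apart from the ratio of the means. A peak was called where the adjusted p of limma was under 0.05. These p-values measure the spread between these libraries, part of which may be technical, because the series describes pools of 2 or 3 biological replicates and lists up to 7 libraries per group. Coordinates are mm10, and each peak was given to the nearest protein-coding gene within 100000 bp. Peaks lay at a gene end (within 1000 bp), within a gene (intragenic) or between genes (intergenic).

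In young endogenous cells the question was which regions separated Tterm (n = 5) from Tprog (n = 4). Slamf6 and Havcr2, the gene of Tim-3, were sorted on and only check the labels: Slamf6 was lower in Tterm (chromosome 1, 171965219 to 171966780, intergenic, 100.03 ± 16.98 against 362 ± 60.3, log2 -1.85 ± 0.21) and Havcr2 was higher (chromosome 11, 46452527 to 46456391, gene end, 1586 ± 108 against 714 ± 16.5, log2 1.15 ± 0.10). Tcf7, which encodes the progenitor transcription factor TCF-1, was lower (chromosome 11, 52273730 to 52276115, intragenic, 210.0 ± 37.3 against 1022 ± 126, log2 -2.29 ± 0.14, adjusted p 6.61e-12). Ccr7, a lymph node homing receptor, was lower as well (chromosome 11, 99170666 to 99171753, intergenic, 51.2 ± 13.0 against 569 ± 33.2, log2 -3.49 ± 0.21, adjusted p 6.61e-12). Id3, which encodes an inhibitor of E proteins and marks less differentiated cells, was lower (chromosome 4, 136106328 to 136107477, intergenic, 120.5 ± 37.7 against 735 ± 40.2, log2 -2.66 ± 0.20). The quiescence factor Foxp1 (chromosome 6, 99485225 to 99486781, intragenic, 70.9 ± 15.1 against 468 ± 70.4, log2 -2.72 ± 0.19) and the chromatin organizer Satb1 (chromosome 17, 51879085 to 51880796, intergenic, 84.5 ± 15.5 against 433 ± 40.2, log2 -2.36 ± 0.21) were lower in Tterm. The chemokine gene Xcl1 was lower (chromosome 1, 164989274 to 164990415, intergenic, 45.6 ± 11.2 against 257 ± 20.9, log2 -2.50 ± 0.21). The AP-1 subunit gene Jun was also lower (chromosome 4, 95096645 to 95097296, intergenic, 27.4 ± 8.35 against 247 ± 82.3, log2 -3.12 ± 0.27).

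In young Tterm Gzmb, which encodes a granule protease, was higher (chromosome 14, 56261599 to 56263015, gene end, 1142 ± 115 against 494 ± 10.8, log2 1.201 ± 0.11), and its relative Gzmk was higher (chromosome 13, 113167960 to 113170695, gene end, 1486 ± 77.1 against 703 ± 48.2, log2 1.08 ± 0.11). Runx3, a transcription factor of cytotoxic cells, was higher at an intragenic peak (chromosome 4, 135168164 to 135169936, intragenic, 1382 ± 139 against 469.7 ± 24.9, log2 1.55 ± 0.11). Ccl3, a chemokine of activated T cells, was higher (chromosome 11, 83628513 to 83630263, intergenic, 1426 ± 167 against 447 ± 55.6, log2 1.67 ± 0.15). Nfatc2, which acts downstream of the T cell receptor, was higher too (chromosome 2, 168428517 to 168430391, intergenic, 866 ± 100.8 against 297 ± 54.6, log2 1.55 ± 0.13). Pdcd1, which encodes PD-1, was higher (chromosome 1, 94047999 to 94049015, intragenic, 745 ± 125 against 441 ± 13.8, log2 0.74 ± 0.13). Tox, a transcription factor of exhausted cells, had its lowest-p peak lower in Tterm (chromosome 4, 6934288 to 6935905, intragenic, 221 ± 47.0 against 485 ± 107, log2 -1.13 ± 0.19). Lef1 belongs to the progenitor list, and 1 distal peak given to it was higher in Tterm (chromosome 3, 131056963 to 131057951, intergenic, 1093 ± 233 against 283 ± 64.1, log2 1.94 ± 0.16).

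Among all called peaks with library values that did not overlap, the largest differences in young cells included genes of no list. B4galnt2, a glycosyltransferase gene, was higher in Tterm (chromosome 11, 95905878 to 95906458, intragenic, 268 ± 52.1 against 26.1 ± 7.28, log2 3.33 ± 0.25, adjusted p 2.45e-10). The death-associated kinase gene Dapk2 was also higher (chromosome 9, 66232222 to 66232719, intragenic, 59.3 ± 14.7 against 5.85 ± 6.61, log2 3.70 ± 0.54). Nrf1, a regulator of respiratory genes, was higher (chromosome 6, 30114235 to 30114569, intragenic, 45.6 ± 12.2 against 4.02 ± 3.05, log2 3.52 ± 0.58). H60c, which encodes a ligand of NKG2D, was higher too (chromosome 10, 3198447 to 3199087, intergenic, 46.1 ± 18.3 against 5.72 ± 8.89, log2 3.66 ± 0.66). Lonrf2 was lower in Tterm (chromosome 1, 38723217 to 38724573, intergenic, 18.8 ± 11.6 against 325 ± 32.0, log2 -4.23 ± 0.37, adjusted p 2.28e-09). Ift80, which encodes a transport protein of cilia, was also lower (chromosome 3, 68966589 to 68967894, intragenic, 22.7 ± 11.9 against 362 ± 45.4, log2 -4.08 ± 0.33). Prkg1, a kinase gene, was lower (chromosome 19, 31321702 to 31322231, intragenic, 7.84 ± 5.49 against 110.4 ± 38.0, log2 -4.05 ± 0.62). Stx11, which takes part in granule release, was lower (chromosome 10, 12974658 to 12974928, intergenic, 7.45 ± 4.56 against 123 ± 39.7, log2 -3.99 ± 0.63). By limma 10261 peaks were higher and 8115 lower of 71756 tested. Near a gene end lay 30.9% of higher and 11.1% of lower peaks (aged cells 9.99% and 8.84%), against 19.97% of those tested. The split rested on the scaling: with equal totals 6025 were higher and 11249 lower, and the median of all peaks was -0.17.

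The gene lists were fixed beforehand, and their peaks were counted in young Tterm against Tprog. All 19 progenitor exhausted genes had a lower peak, 8 of them also a higher one: 149 of 298 peaks were lower and 15 higher (158 and 16 adjusted over the list alone), with a list median of -0.66. The test at a preset correlation gave an adjusted p of 1.14e-19, and with the estimated correlation the p was 0.0846. Of the terminally exhausted genes 16 had a higher peak, among them Havcr2, Ccl3 and Pdcd1, while Tox, Eomes and Nr4a1 had only lower ones: 55 peaks were higher and 26 lower (61 and 28 adjusted over the list alone). Their median was 0.13, which turned to -0.03 with equal totals, and the adjusted p was 0.0122 (estimated-correlation p 0.485). Of the effector genes 13 had a higher peak, among them Gzmb and Gzmk, with 71 peaks higher and 15 lower (75 and 16 adjusted over the list alone). The effector median was 0.49 and the adjusted p 7.22e-09 (estimated-correlation p 0.0846). Tissue residency peaks, such as those of Runx3 and Cxcr6, were higher in 40 cases and lower in 11 (47 and 12 adjusted over the list alone), with an adjusted p of 0.000528 (estimated-correlation p 0.350).

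The other 11 lists did not pass the set test in young Tterm against Tprog. T cell receptor and costimulation peaks were higher in 30 cases and lower in 36 (34 and 40 adjusted over the list alone). Age-associated genes had 20 higher peaks, among them peaks of Ccl5, Gzmk, Itga4, Lag3, Nr4a2 and Pdcd1, and 16 lower ones, at Eomes, Nr4a2 and Tox. For AP-1 genes 8 peaks were higher and 15 lower, with Jun, Fos and Fosb lower. Of the cell cycle genes 12 had a higher peak, 13 peaks in all, against 3 lower. Interferon response peaks were higher in 11 cases and lower in 3 (13 and 4 adjusted over the list alone), and virtual memory peaks in 8 and 12 (11 and 15 adjusted over the list alone). Of the lists of other cell types, NK cell peaks were higher in 5 cases, at Fcer1g and Klrb1c, and lower in 2, and CD4 and regulatory T cell peaks were higher in 7 and lower in 12. Myeloid peaks were higher in 4 cases and lower in 9, and B cell peaks in 2 and 5. Of the melanocyte and melanoma list 1 peak, at Sox10, was higher.

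**Figure D1:**
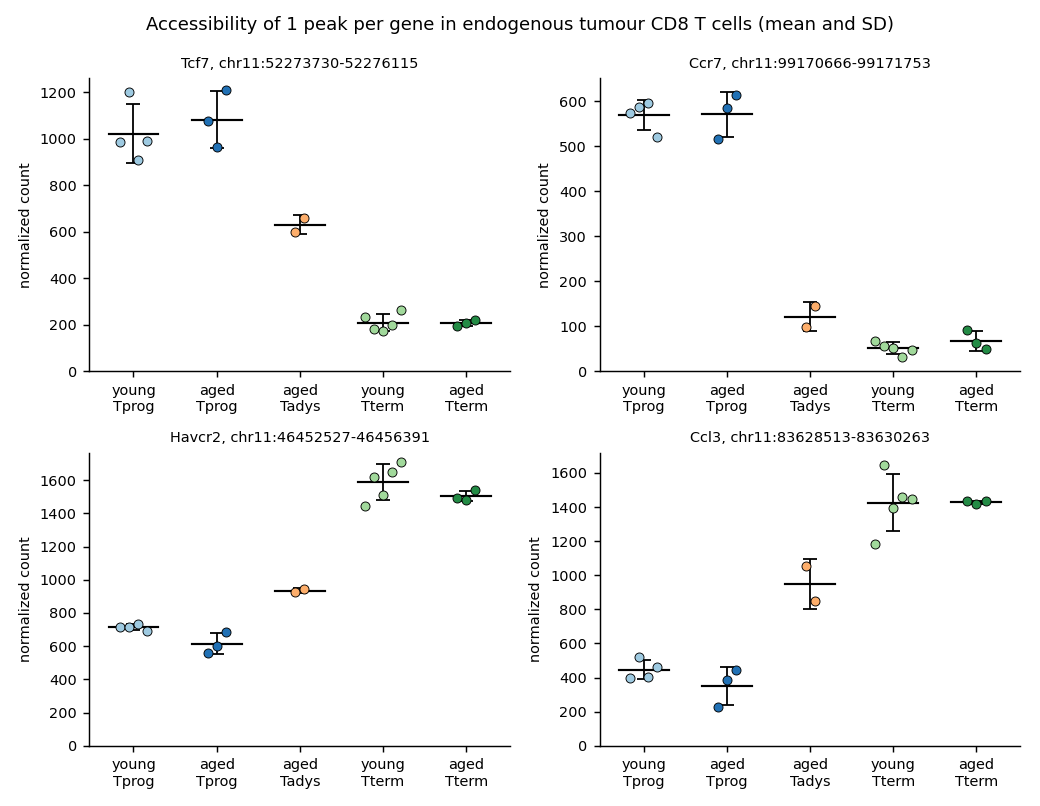
Normalized reads (vertical axis) of peaks at Tcf7, Ccr7, Havcr2 and Ccl3 in each endogenous group (horizontal axis). Each point is 1 library, with lines at the mean and bars of SD, and the Tcf7 mean was 1022 in young Tprog and 631 in Tadys.

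The same comparison in aged cells (n = 3 and n = 3) called 4843 higher and 3856 lower peaks in Tterm, and with equal totals 4380 and 4443. Tcf7 was lower at the same peak (208 ± 14.2 against 1083 ± 122, log2 -2.37 ± 0.17, adjusted p 1.5e-09). Ccr7 was lower too (67.7 ± 21.6 against 571 ± 50.4, log2 -3.10 ± 0.26). Foxp1 was lower at the same peak (101.1 ± 22.8 against 508 ± 71.7, log2 -2.33 ± 0.23), and Id3 at a peak near the gene (chromosome 4, 136143484 to 136144992, gene end, 234 ± 23.5 against 631 ± 43.7, log2 -1.43 ± 0.17). Ccl3 was higher (1429 ± 8.58 against 352 ± 112, log2 2.07 ± 0.18). Runx3 was also higher (1343 ± 31.1 against 557 ± 89.2, log2 1.28 ± 0.13). Nfatc2 was higher too (777 ± 43.9 against 297 ± 2.83, log2 1.38 ± 0.16). Prf1, which encodes the pore-forming protein of cytotoxic granules, was higher (chromosome 10, 61300061 to 61300358, intragenic, 203 ± 33.8 against 41.1 ± 12.6, log2 2.30 ± 0.29). Cd244a, an inhibitory receptor gene, was higher (chromosome 1, 171558664 to 171561490, gene end, 605 ± 47.7 against 204 ± 9.68, log2 1.56 ± 0.17). Fcer1g, a signalling adaptor shared with NK cells, was also higher (chromosome 1, 171231491 to 171233226, intragenic, 443 ± 64.6 against 128 ± 18.2, log2 1.78 ± 0.20). Id2, an inhibitor of E proteins like Id3, was higher (chromosome 12, 25164283 to 25166408, intergenic, 723 ± 50.9 against 311 ± 46.6, log2 1.22 ± 0.15). Havcr2 (1505 ± 31.9 against 615 ± 62.1, log2 1.29 ± 0.12) and Slamf6 (111 ± 30.4 against 313 ± 50.9, log2 -1.52 ± 0.26) moved as sorted.

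Gzmb (1026 ± 22.3 against 534 ± 44.0, log2 0.94 ± 0.13), Gzmk (1149.8 ± 157 against 765 ± 100.7, log2 0.59 ± 0.13) and Pdcd1 (826 ± 96.0 against 448 ± 60.6, log2 0.88 ± 0.16) were higher in aged Tterm at the peaks given for young cells, and Tox was lower (235 ± 43.2 against 578 ± 37.2, log2 -1.31 ± 0.23). Among the largest gains was a distal peak of the cytokine gene Ifng (chromosome 10, 118482544 to 118482910, intergenic, 103 ± 31.9 against 4.55 ± 6.21, log2 4.89 ± 0.63, adjusted p 5.15e-06). The cyclin-dependent kinase gene Cdk14 was higher (chromosome 5, 5377761 to 5378235, intragenic, 133 ± 17.9 against 12.1 ± 11.05, log2 4.23 ± 0.68). Lonrf2 was lower again (13.7 ± 7.88 against 177 ± 20.6, log2 -3.78 ± 0.45). The stem cell receptor gene Lgr5 was lower too (chromosome 10, 115596759 to 115597325, intergenic, 6.57 ± 3.79 against 90.4 ± 26.5, log2 -3.69 ± 0.61). Of the progenitor genes 18 of 19 had a lower peak, with 98 lower and 6 higher peaks (116 and 8 adjusted over the list alone) and an adjusted p of 3.58e-20 (estimated-correlation p 0.107). Terminally exhausted peaks were higher in 46 cases and lower in 10 (53 and 12 adjusted over the list alone, adjusted p 0.0254, estimated-correlation p 0.689), and their median of 0.03 turned to -0.02 with equal totals. Effector peaks were higher in 39 cases and lower in 8 (52 and 10 adjusted over the list alone), with an adjusted p of 5.99e-06 (estimated-correlation p 0.246). Without aged Tterm 3 the count was 5402.

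The question of the age by subset test was whether Tterm and Tprog differed in another way in aged than in young cells. By limma 0 of 71756 peaks passed, with 5676 under 0.05 before adjustment, and by edgeR 0 and by DESeq2 19 passed. The interferon response list had a median of -0.23 and an adjusted p of 0.0182 (estimated-correlation p 0.5263). With equal totals the median of all peaks moved by 0.12, and without young Tprog 3 the count was 1.

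In endogenous Tterm, aged (n = 3) against young (n = 5), 5 peaks were higher and 1 lower of 71756. Tnfsf11, which encodes the cytokine RANKL, was higher at a distal peak (chromosome 14, 78329491 to 78331126, intergenic, 345 ± 47.9 against 153 ± 31.6, log2 1.18 ± 0.18, adjusted p 0.00580). Odc1, the rate-limiting enzyme gene of polyamine synthesis, was higher near its end (chromosome 12, 17551253 to 17554724, gene end, 1049.9 ± 65.7 against 573 ± 81.8, log2 0.88 ± 0.12, adjusted p 0.00333). The semaphorin gene Sema6d (chromosome 2, 124636430 to 124637868, intragenic, 201.5 ± 25.7 against 79.8 ± 14.6, log2 1.34 ± 0.21) and the sialyltransferase gene St6gal1 (chromosome 16, 23287573 to 23288646, intragenic, 164 ± 23.8 against 66.3 ± 15.2, log2 1.31 ± 0.23) were higher. A region far from any gene was higher (chromosome 1, 98727437 to 98728153, intergenic, 51.9 ± 3.98 against 7.42 ± 3.63, log2 2.75 ± 0.43). Fam155a was lower at a distal peak (chromosome 8, 9824102 to 9824945, intergenic, 16.8 ± 2.84 against 122 ± 29.5, log2 -2.77 ± 0.35, adjusted p 0.000874). The list genes followed by rule did not pass: Gzmk (chromosome 13, 113167960 to 113170695, gene end, 1149.8 ± 157 against 1486 ± 77.1, log2 -0.38 ± 0.12, adjusted p 0.439), Tcf7 (chromosome 11, 52280792 to 52284473, gene end, 296 ± 23.3 against 218 ± 21.9, log2 0.44 ± 0.15, adjusted p 0.490), Tox (chromosome 4, 6838191 to 6839032, 84.8 ± 36.8 against 135 ± 33.7, adjusted p 0.614), Gzmb (chromosome 14, 56303632 to 56304490, 76.0 ± 44.0 against 101.5 ± 27.2, adjusted p 0.776) and Pdcd1 (chromosome 1, 94074135 to 94075668, 1409.8 ± 206 against 1214 ± 325, adjusted p 0.858). The progenitor list median was 0.14 (adjusted p 0.000113, estimated-correlation p 0.692), and that of the cell cycle list was -0.12 (adjusted p 0.00591, estimated-correlation p 0.289). Before adjustment 5122 peaks were under 0.05. The count was 12 with equal totals, 97 with array weights, 27 with edgeR, 268 with DESeq2, 27 in a fit of these groups alone and 0 with a replicate block. Without young Tterm 1 it was 12, without young Tterm 3 it was 14, without aged Tterm 2 it was 2 and without aged Tterm 3 it was 1.

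In endogenous Tprog, aged (n = 3) against young (n = 4), 59 peaks were higher and 60 lower. A distal peak given to the ribosomal gene Rpl37a was higher (chromosome 1, 72754801 to 72755658, intergenic, 142 ± 45.03 against 23.3 ± 5.40, log2 2.54 ± 0.42, adjusted p 0.0159). Epha3, an ephrin receptor gene, was higher (chromosome 16, 63856661 to 63857878, intragenic, 218 ± 31.2 against 54.9 ± 21.5, log2 2.05 ± 0.35, adjusted p 0.0159). Rbms3, an RNA-binding protein gene, was also higher (chromosome 9, 117399872 to 117400865, intragenic, 168 ± 43.8 against 36.4 ± 24.3, log2 2.32 ± 0.42). The nuclear corepressor gene Nrip1 was higher too (chromosome 16, 76432867 to 76433614, intergenic, 89.7 ± 40.3 against 19.4 ± 13.2, log2 2.28 ± 0.48). Itpripl2 (chromosome 7, 118476340 to 118476888, intergenic, 176 ± 31.8 against 46.1 ± 20.8, log2 2.07 ± 0.39) and Col28a1 (chromosome 6, 7940348 to 7941385, intergenic, 108 ± 4.30 against 29.1 ± 7.65, log2 1.89 ± 0.34) were higher. The growth factor gene Igf2 was lower (chromosome 7, 142664217 to 142664496, intragenic, 1.504 ± 1.32 against 34.0 ± 6.37, log2 -3.98 ± 0.59, adjusted p 0.00885). Setbp1 was also lower (chromosome 18, 79015460 to 79016236, intragenic, 9.21 ± 8.53 against 61.7 ± 15.5, log2 -3.36 ± 0.63). Ndfip2, an adaptor of ubiquitin ligases, was lower (chromosome 14, 105359842 to 105360296, intergenic, 6.10 ± 7.27 against 33.0 ± 5.93, log2 -2.97 ± 0.56). Tox4 was lower too (chromosome 14, 52289901 to 52290510, intragenic, 10.7 ± 9.51 against 59.2 ± 24.8, log2 -2.59 ± 0.53). Fam155a was lower at the peak that was lower in aged Tterm (12.9 ± 2.33 against 69.2 ± 14.6, log2 -2.33 ± 0.37, adjusted p 0.0121).

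Among list genes in Tprog, Ebf1, a transcription factor of B cells, was lower with age (chromosome 11, 44894687 to 44895282, intragenic, 24.2 ± 9.90 against 93.5 ± 3.37, log2 -1.98 ± 0.40, adjusted p 0.0301). Genes followed by rule did not pass: Gzmb (chromosome 14, 56303632 to 56304490, 116 ± 12.8 against 62.4 ± 13.7, adjusted p 0.309), Tox (chromosome 4, 6792074 to 6793624, 135 ± 15.1 against 86.5 ± 24.7, adjusted p 0.317), Gzmk (chromosome 13, 113182480 to 113184097, 613 ± 132 against 469 ± 87.2, adjusted p 0.390), Tcf7 (chromosome 11, 52260697 to 52262205, 428 ± 76.7 against 519 ± 94.9, adjusted p 0.539) and Pdcd1 (chromosome 1, 94074135 to 94075668, 961 ± 132 against 778 ± 173, adjusted p 0.541). The myeloid list had a median of -0.34 (adjusted p 0.0102, estimated-correlation p 0.230). Its mean was 6.93 or more in young and 6.76 or less in aged Tprog, and that of the B cell list 5.82 or more and 5.76 or less. Whether the aged sort held fewer other cells was not tested. Age-associated genes had a median of 0.14 (adjusted p 0.0228, estimated-correlation p 0.723) and interferon response genes 0.16 (adjusted p 0.0303, estimated-correlation p 0.589). Tissue residency peaks passed only when adjusted over the list alone, 6 higher and 2 lower. Near a gene end lay 6.67% of the lower peaks, against 19.97% of those tested. With equal totals 53 peaks were higher and 107 lower, with array weights 248 passed, with DESeq2 674 and with a replicate block 43. Without aged Tprog 2 the count was 186 and without aged Tprog 1 it was 15, and without young Tprog 1, 2, 3 and 4 it was 76, 46, 50 and 18.

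The age differences of Tterm and Tprog shared no library and were compared across 71756 peaks, which are not independent replicates. Their log2 differences had a correlation of 0.135, and 1 peak, that of Fam155a, was called in both. Of the peaks called in Tterm 6 of 6, and of those called in Tprog 95 of 119, had the same sign in the other subset. The correlation was 0.0327 without aged Tterm 1 and 0.0779 without young Tterm 5.

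Tadys (n = 2) was first compared with aged Tterm (n = 3). Tcf7 was higher in Tadys (631 ± 42.2 against 208 ± 14.2, log2 1.60 ± 0.19, adjusted p 4.49e-05). Foxp1 was also higher (301 ± 86.7 against 101.1 ± 22.8, log2 1.56 ± 0.26). A distal peak of Id3 was higher too (chromosome 4, 136122877 to 136123895, intergenic, 219 ± 23.4 against 61.1 ± 6.78, log2 1.83 ± 0.29). Ifng was lower at a distal peak (chromosome 10, 118486139 to 118488184, intergenic, 298 ± 25.1 against 768 ± 96.3, log2 -1.36 ± 0.19). Gzmk was lower (554 ± 38.1 against 1149.8 ± 157, log2 -1.04 ± 0.15). Gzmb was lower at a distal peak (chromosome 14, 56281560 to 56281963, intergenic, 102 ± 22.9 against 224 ± 18.0, log2 -1.14 ± 0.23). Rgs1, which limits chemokine signalling, was lower (chromosome 1, 144300505 to 144302011, intergenic, 237.8 ± 69.9 against 564 ± 55.7, log2 -1.27 ± 0.22). Pdcd1 was lower near the gene (chromosome 1, 94051042 to 94056803, gene end, 2255 ± 573 against 3695 ± 49.4, log2 -0.74 ± 0.13, adjusted p 0.00197). Batf3, a partner of AP-1, was lower (chromosome 1, 191104568 to 191104977, intragenic, 85.9 ± 5.29 against 234 ± 33.5, log2 -1.43 ± 0.27). Nfatc2 was lower at an intragenic peak (chromosome 2, 168578296 to 168578650, intragenic, 22.7 ± 6.58 against 78.2 ± 5.52, log2 -1.77 ± 0.33), and the distal peak of Lef1 that was higher in Tterm was lower (536 ± 140.2 against 1172 ± 136, log2 -1.15 ± 0.22). Havcr2, sorted on, was lower (chromosome 11, 46473712 to 46475055, intragenic, 304 ± 16.6 against 605 ± 43.6, log2 -0.99 ± 0.17), and Slamf6 and Tox did not pass, with adjusted p 0.153 and 0.0839.

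The largest differences of Tadys from Tterm lay elsewhere. Rasgef1c, a guanine nucleotide exchange factor gene, was higher (chromosome 11, 49934106 to 49934350, intragenic, 47.0 ± 21.4 against 1.83 ± 0.902, log2 4.07 ± 1.02). Rev3l, which encodes a DNA polymerase subunit, was lower (chromosome 10, 39811448 to 39811789, intragenic, 0.760 ± 1.07 against 60.4 ± 30.5, log2 -5.16 ± 0.71). The zinc finger gene Zfp148 was also lower (chromosome 16, 33403973 to 33404393, intragenic, 3.04 ± 4.30 against 64.2 ± 13.3, log2 -4.60 ± 0.56, adjusted p 5.66e-05). By limma 1481 peaks were higher and 3037 lower. Near a gene end lay 25.2% of the lower and 8.91% of the higher peaks. Effector peaks were lower in 25 cases and higher in 3 (40 and 4 adjusted over the list alone), with an adjusted p of 1.18e-08 (estimated-correlation p 0.164). Tadys 1 had the lowest effector mean of the aged libraries (7.13), while its myeloid (7.15) and B cell means (5.93) lay above every aged Tterm library. Terminally exhausted peaks were lower in 19 cases and higher in 2 (29 and 2 adjusted over the list alone), with an adjusted p of 0.00370 (estimated-correlation p 0.505). Tissue residency peaks were lower in 15 cases (19 lower and 1 higher adjusted over the list alone), with an adjusted p of 0.000498 (estimated-correlation p 0.475). Progenitor peaks were higher in 29 cases, at 10 genes, and lower in 7 (34 and 8 adjusted over the list alone), with an adjusted p of 0.00838 (estimated-correlation p 0.643), while the progenitor mean of Tadys 1 (6.92) lay within aged Tterm and only that of Tadys 2 (7.29) lay above. The CD4 and regulatory T cell list, with Ctla4 and Ikzf2 lower, had a median of -0.27 (adjusted p 0.0414, estimated-correlation p 0.505). With equal totals 1918 peaks were higher and 2166 lower, with array weights 690 passed and in a fit of these groups alone 678. Without Tadys 1 the count was 2031, without aged Tterm 1 it was 2088 and without aged Tterm 3 it was 1713.

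Against aged Tprog (n = 3), Tadys was lower at Tcf7 (631 ± 42.2 against 1083 ± 122, log2 -0.77 ± 0.19, adjusted p 0.0144) and at Ccr7 (121 ± 32.6 against 571 ± 50.4, log2 -2.25 ± 0.29, adjusted p 9.63e-05). Satb1 was lower (103 ± 55.6 against 410.3 ± 93.9, log2 -2.06 ± 0.28), as was Jun (36.0 ± 2.77 against 188 ± 20.3, log2 -2.35 ± 0.37). S1pr1, a receptor for exit from tissue, was lower (chromosome 3, 115675155 to 115676439, intergenic, 128 ± 53.3 against 382 ± 39.1, log2 -1.63 ± 0.30). Cd69, an early activation gene, was lower too (chromosome 6, 129265491 to 129268442, gene end, 307 ± 14.8 against 687 ± 39.2, log2 -1.16 ± 0.20). Gzmb was lower at a distal peak (chromosome 14, 56303632 to 56304490, intergenic, 24.4 ± 10.9 against 116 ± 12.8, log2 -2.27 ± 0.45). Gzmk was lower (chromosome 13, 113180185 to 113181300, gene end, 128 ± 38.7 against 230.1 ± 49.8, log2 -0.85 ± 0.26). Ccl3 was higher (949 ± 145 against 352 ± 112, log2 1.48 ± 0.20), with Runx3 (1079 ± 38.7 against 557 ± 89.2, log2 0.96 ± 0.15). Nfatc1 was higher (chromosome 18, 80545822 to 80546903, intergenic, 164 ± 20.8 against 44.7 ± 9.15, log2 1.86 ± 0.35). Entpd1, which encodes the ectonucleotidase CD39, was also higher (chromosome 19, 40686499 to 40688017, intragenic, 408 ± 61.0 against 194 ± 30.5, log2 1.07 ± 0.20). Slamf6, sorted on, was lower (chromosome 1, 171920911 to 171922141, intragenic, 132 ± 41.6 against 458 ± 89.2, log2 -1.81 ± 0.28), Havcr2 was higher (935 ± 16.1 against 615 ± 62.1, log2 0.61 ± 0.13), and Pdcd1 did not pass (adjusted p 0.255).

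Among the largest differences from Tprog, Ephb3, an ephrin receptor gene, was higher (chromosome 16, 21206604 to 21206868, intragenic, 54.2 ± 2.91 against 2.45 ± 2.16, log2 4.30 ± 0.71). The kinase gene Rps6ka2 was higher too (chromosome 17, 7205057 to 7205526, intragenic, 47.8 ± 11.7 against 3.84 ± 6.66, log2 4.37 ± 1.07). Il6st, which encodes the shared signal subunit of the IL-6 receptor family, was lower (chromosome 13, 112443264 to 112443804, intergenic, 6.84 ± 9.67 against 96.9 ± 30.8, log2 -4.62 ± 0.62). By limma 1871 peaks were higher and 2902 lower, and 25.6% of the lower peaks lay near a gene end. Progenitor peaks were lower in 39 cases, at 12 genes (58 lower and 1 higher adjusted over the list alone), with an adjusted p of 1.28e-10 (estimated-correlation p 0.469). Age-associated peaks were lower in 9 cases (19 lower and 1 higher adjusted over the list alone), with an adjusted p of 0.0207 (estimated-correlation p 0.633), while the mean of Tadys 2 (7.16) lay within aged Tprog. Tadys 1 lay above every aged Tprog library in the myeloid, B cell and melanocyte means (7.15, 5.93 and 6.38). The CD4 and regulatory T cell list had 4 lower peaks and a median of -0.33 (adjusted p 0.00422, estimated-correlation p 0.469), and 3 NK cell peaks, at Fcer1g, Klrb1c and Tyrobp, were higher. With array weights 426 peaks passed and in a fit of these groups alone 398. Without Tadys 1 the count was 1368, without aged Tprog 2 it was 1848 and without aged Tprog 3 it was 2678.

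A score placed Tadys between the other aged subsets. It was the mean log2 level over 11000 peaks higher in young Tterm than Tprog, minus that over 8901 lower, from a fit of young libraries only. Aged Tprog scored 1.06 ± 0.11 (n = 3), Tadys 1.66 ± 0.089 (n = 2) and aged Tterm 2.48 ± 0.037 (n = 3). Tadys libraries lay 37.9% and 46.7% of the way from aged Tprog to Tterm, with 500 peaks per direction 45.1% and 57.8%, and with quantile scaling 39.2% and 59.9%. Tadys minus Tterm was -0.82 and minus Tprog 0.60 (exact permutation p 0.1 each, the smallest for 10 splits). With 500 peaks per direction they were -1.52 and 1.61. The peaks of Tcf7 and Ccl3 showed the same order of groups.

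**Figure D2:**
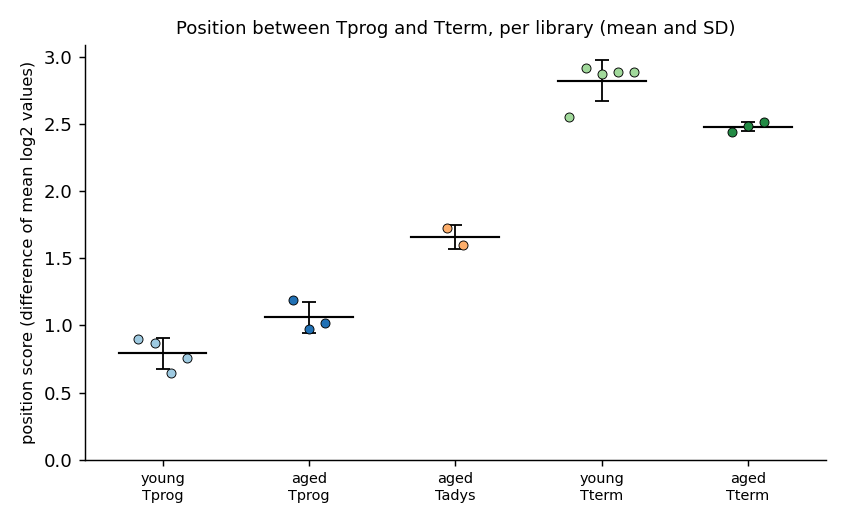
Position score (vertical axis) of each endogenous group (horizontal axis), from peaks defined in the young groups. Each point is 1 library, with lines at the mean and bars of SD, and the aged means were 1.06 for Tprog, 1.66 for Tadys and 2.48 for Tterm.

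Young OT-1 Tterm (n = 7) against young naive cells (n = 2) served as a check of the labels, because tissue, differentiation and batch all coincide there. Runx3 was higher (chromosome 4, 135168055 to 135169873, intragenic, 1011 ± 201.3 against 94.7 ± 2.15, log2 3.35 ± 0.22). Gzmb was also higher (chromosome 14, 56261669 to 56263049, gene end, 743 ± 128 against 93.1 ± 4.43, log2 2.94 ± 0.26). Pdcd1 was higher too (chromosome 1, 94074078 to 94075668, intergenic, 879.6 ± 176 against 100.3 ± 12.6, log2 3.07 ± 0.32). Havcr2 was also higher (chromosome 11, 46452461 to 46455538, gene end, 928 ± 245 against 111 ± 24.9, log2 3.00 ± 0.23). Tcf7 was lower (chromosome 11, 52273560 to 52276172, intragenic, 123 ± 25.1 against 679 ± 10.5, log2 -2.53 ± 0.25). Ccr7 was lower too (chromosome 11, 99170657 to 99171760, intergenic, 34.2 ± 10.5 against 427 ± 8.55, log2 -3.72 ± 0.30). By limma 18877 peaks were higher and 15020 lower of 84091. With equal totals 17018 were higher and 21934 lower, and the median of all peaks stood at -0.26. Effector peaks were higher in 107 cases, against 14 lower, with an adjusted p of 2.44e-14 (estimated-correlation p 0.277). Without young naive 1 the count was 19578 and without young naive 2 it was 19496.

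In young OT-1 cells, Tterm (n = 7) against Tprog (n = 2) asked whether cells of 1 antigen specificity split as endogenous cells did. Ccr7 was lower in Tterm (chromosome 11, 99170657 to 99171760, intergenic, 34.2 ± 10.5 against 355 ± 34.1, log2 -3.45 ± 0.30, adjusted p 1.14e-07). Tcf7 was also lower (chromosome 11, 52273560 to 52276172, intragenic, 123 ± 25.1 against 732 ± 78.8, log2 -2.64 ± 0.25). Id3 was lower (chromosome 4, 136106476 to 136107365, intergenic, 45.9 ± 17.2 against 654 ± 96.0, log2 -3.65 ± 0.38). Satb1 was lower too (chromosome 17, 51878992 to 51880899, intergenic, 52.7 ± 16.5 against 277 ± 34.6, log2 -2.45 ± 0.27). Foxp1 was also lower (chromosome 6, 99485096 to 99486766, intragenic, 53.8 ± 13.1 against 314 ± 15.3, log2 -2.60 ± 0.26). Tnfrsf9, which encodes the costimulatory receptor 4-1BB, was lower (chromosome 4, 150939566 to 150940624, intragenic, 33.2 ± 7.08 against 249 ± 21.9, log2 -2.93 ± 0.29). The adaptor gene Lat was lower too (chromosome 7, 126339337 to 126341042, intergenic, 113 ± 27.6 against 500.03 ± 15.3, log2 -2.20 ± 0.24). Prdm1, which encodes Blimp-1, was higher (chromosome 10, 44449789 to 44451107, intragenic, 343 ± 60.9 against 66.8 ± 12.8, log2 2.30 ± 0.25). Entpd1 was also higher (chromosome 19, 40659322 to 40662504, intragenic, 650.1 ± 116 against 185 ± 18.6, log2 1.76 ± 0.21). Ccl4 was higher too (chromosome 11, 83665447 to 83666912, gene end, 226 ± 29.3 against 55.9 ± 14.0, log2 1.99 ± 0.24). Gzmb was also higher (chromosome 14, 56275699 to 56276789, intergenic, 97.0 ± 36.3 against 14.6 ± 14.0, log2 2.74 ± 0.39). Gzmk was higher (chromosome 13, 113182483 to 113184098, intergenic, 478 ± 57.4 against 268 ± 23.4, log2 0.80 ± 0.22). Tox was lower (chromosome 4, 6940656 to 6941734, intragenic, 109 ± 40.7 against 298 ± 40.0, log2 -1.28 ± 0.27). Slamf6 (chromosome 1, 171965284 to 171966671, intergenic, 38.2 ± 7.69 against 246 ± 30.9, log2 -2.68 ± 0.33) and Havcr2 (chromosome 11, 46452461 to 46455538, gene end, 928 ± 245 against 402 ± 40.0, log2 1.14 ± 0.23) moved as sorted, and Pdcd1 did not pass (chromosome 1, 94078365 to 94079742, intergenic, 319 ± 80.1 against 174 ± 54.0, log2 0.79 ± 0.34, adjusted p 0.174).

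Among the largest differences in young OT-1 cells, Upf1, a gene of RNA decay, was higher (chromosome 8, 70341724 to 70342614, intragenic, 557 ± 138 against 20.2 ± 8.08, log2 4.66 ± 0.88). The adhesion receptor gene Adgrg3 was higher too (chromosome 8, 95020184 to 95021318, intragenic, 507 ± 225 against 22.8 ± 7.22, log2 4.22 ± 0.31, adjusted p 9.98e-09). Gcnt3 was lower (chromosome 9, 70039638 to 70040670, gene end, 14.6 ± 4.58 against 352 ± 0.777, log2 -4.53 ± 0.38). Lonrf2 (chromosome 1, 38723278 to 38724334, intergenic, 10.1 ± 5.84 against 247 ± 76.1, log2 -4.47 ± 0.54) and Ift80 (chromosome 3, 68966725 to 68967861, intragenic, 13.6 ± 4.75 against 269 ± 76.2, log2 -4.30 ± 0.75) were lower, as in endogenous cells. By limma 3412 peaks were higher and 3001 lower, and within batch 4 and 5 alone 3200 were higher and 3041 lower. With equal totals 3663 were higher and 4154 lower, and the median of all peaks stood at -0.13. Progenitor peaks were lower in 80 cases, at 17 of 19 genes, and higher in 6 (117 and 8 adjusted over the list alone), with an adjusted p of 2.91e-13 (estimated-correlation p 0.0595). Terminally exhausted peaks were higher in 31 cases and lower in 12 (43 and 15 adjusted over the list alone), with an adjusted p of 0.000225 (estimated-correlation p 0.631). Effector peaks were higher in 48 cases and lower in 8 (59 and 10 adjusted over the list alone), with an adjusted p of 2.20e-10 (estimated-correlation p 0.562). Across 64998 overlapping peak pairs, which are not independent replicates, the endogenous and OT-1 differences had a correlation of 0.726, and 5063 of 5068 peaks called in both had the same direction. With array weights 13368 peaks passed and with a replicate block 3766. Without young Tprog 1 the count was 2781 and without young Tprog 2 it was 1884.

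In aged OT-1 cells, Tterm (n = 6) against Tprog (n = 2), Entpd1 was higher (chromosome 19, 40691595 to 40692561, intragenic, 402 ± 53.2 against 39.4 ± 21.1, log2 3.54 ± 0.33, adjusted p 5.14e-07). Ifng was higher at a distal peak (chromosome 10, 118385923 to 118387701, intergenic, 382 ± 69.8 against 59.8 ± 0.680, log2 2.69 ± 0.26). Ccl3 was also higher (chromosome 11, 83628406 to 83630287, intergenic, 1314 ± 208 against 185 ± 61.1, log2 2.94 ± 0.32). Ccl4 was higher too (chromosome 11, 83665447 to 83666912, gene end, 254 ± 29.4 against 53.8 ± 25.1, log2 2.34 ± 0.29). Runx3 was higher (chromosome 4, 135168055 to 135169873, intragenic, 1055 ± 174 against 208 ± 53.5, log2 2.44 ± 0.27). Gzmb was also higher (chromosome 14, 56281534 to 56282077, intergenic, 173 ± 25.4 against 49.2 ± 16.9, log2 1.92 ± 0.29). Pdcd1 was higher too (chromosome 1, 94050983 to 94051596, gene end, 237 ± 33.3 against 66.4 ± 4.90, log2 1.86 ± 0.28). Myb, a progenitor list gene, was higher at 1 peak (chromosome 10, 21115182 to 21116081, intergenic, 190.5 ± 44.3 against 27.5 ± 12.1, log2 2.86 ± 0.32). Satb1 was lower (44.7 ± 5.48 against 338 ± 42.9, log2 -2.81 ± 0.32). Tcf7 was also lower (chromosome 11, 52268061 to 52268974, intragenic, 54.0 ± 7.87 against 273 ± 93.0, log2 -2.21 ± 0.28). Ccr7 was lower too (37.1 ± 7.18 against 301 ± 68.8, log2 -2.84 ± 0.36). Havcr2 (1039 ± 143 against 189 ± 20.3, log2 2.54 ± 0.28) and Slamf6 (34.8 ± 11.1 against 129.6 ± 66.5, log2 -1.81 ± 0.40) moved as sorted. By limma 9477 peaks were higher and 2850 lower, and with equal totals 5745 and 6047, so the split rested on the scaling, which moved the median of all peaks from 0.15 to -0.25. With quantile scaling 7756 were higher and 4913 lower. Within batch 6 alone 1216 were higher and 732 lower, with 1 Tterm library whose spread was taken from other groups.

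Progenitor peaks in aged OT-1 Tterm were lower in 70 cases and higher in 20 (83 and 24 adjusted over the list alone), with an adjusted p of 2.90e-07 (estimated-correlation p 0.288). Effector peaks such as those of Gzmb and Ifng were higher in 88 cases and lower in 3 (109 and 7 adjusted over the list alone), with an adjusted p of 4.33e-14 (estimated-correlation p 0.288). Terminally exhausted peaks were higher in 71 cases and lower in 8 (93 and 10 adjusted over the list alone), with an adjusted p of 1.04e-06 (estimated-correlation p 0.458). Aged Tprog 1 had lower means than aged Tprog 2 for the effector (5.44 against 6.15) and terminally exhausted lists (5.64 against 6.33). Array weights gave 1861 called peaks, a replicate block 4556 and a fit of these groups alone 203. Without aged Tprog 2 the count was 30254 and without aged Tprog 1 it was 6720.

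For OT-1 Tterm, aged (n = 6) against young (n = 7), 150 peaks were higher and 74 lower of 84091, and within batch 4 and 5 alone 593 were higher and 269 lower. Within batch 6 alone, with 2 young libraries and 1 aged, which has no spread of its own, 0 passed by limma and 1858 were under 0.05 before adjustment. Atp2b4, a calcium pump gene, was higher with age (chromosome 1, 133762810 to 133763835, intragenic, 195 ± 38.0 against 38.2 ± 34.5, log2 2.62 ± 0.34, adjusted p 0.000398). Gm14139 was higher near its end (chromosome 2, 150181219 to 150182236, gene end, 81.0 ± 15.0 against 18.7 ± 18.0, log2 2.63 ± 0.50). Regions far from any gene were higher, such as 1 on chromosome 7 (chromosome 7, 124934330 to 124935538, intergenic, 137 ± 45.8 against 17.5 ± 6.79, log2 2.81 ± 0.32, adjusted p 5.38e-05). Tnfsf8, which encodes the ligand of CD30, was higher (chromosome 4, 63841780 to 63843122, intragenic, 199.997 ± 50.7 against 97.4 ± 21.1, log2 1.00 ± 0.19, adjusted p 0.0120). Ifng was higher at a distal peak (chromosome 10, 118480575 to 118481625, intergenic, 178 ± 33.6 against 103 ± 22.3, log2 0.81 ± 0.17, adjusted p 0.0412). Tenm4 was lower (chromosome 7, 96818050 to 96819154, intragenic, 68.2 ± 23.6 against 184 ± 63.3, log2 -1.60 ± 0.17, adjusted p 3.68e-05). Nav1 was also lower (chromosome 1, 135593691 to 135594733, intragenic, 57.4 ± 17.3 against 206 ± 57.9, log2 -1.83 ± 0.30). Msc, a transcriptional repressor gene, was lower (chromosome 1, 14746920 to 14747925, intergenic, 16.0 ± 14.8 against 78.4 ± 14.9, log2 -2.54 ± 0.55). Myo10 was lower too (chromosome 15, 25623987 to 25624508, intragenic, 34.9 ± 17.5 against 98.96 ± 17.1, log2 -1.503 ± 0.24). On chromosome 5, from 10866105 to 11919464, a cluster with Gm5861, Speer1, Gm6460 and 4933402N22Rik held 19 of the 74 lower peaks. Its gene copies are alike, so reads may be shared between them.

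Other genes of OT-1 Tterm did not pass with age: Tcf7 (chromosome 11, 52318171 to 52319442, 491 ± 103 against 384 ± 63.9, adjusted p 0.617), Pdcd1 (chromosome 1, 94040457 to 94040744, 131 ± 24.7 against 98.7 ± 25.8, adjusted p 0.632), Gzmb (chromosome 14, 56275699 to 56276789, 129 ± 31.8 against 97.0 ± 36.3, adjusted p 0.635), Tox (chromosome 4, 6924060 to 6925568, 246 ± 52.8 against 199 ± 23.1, adjusted p 0.679) and Gzmk (chromosome 13, 113182483 to 113184098, 409 ± 55.1 against 478 ± 57.4, adjusted p 0.764). The progenitor, effector and tissue residency lists had medians of 0.11, 0.13 and 0.12, each with an adjusted p of 0.00717 (estimated-correlation p 0.726). The B cell list had a median of -0.22 (adjusted p 0.0152, estimated-correlation p 0.121). Near a gene end lay 6.00% of the higher peaks, against 18.5% of those tested. Before adjustment 6722 peaks were under 0.05. Counts were 338 at pseudocount 5, 390 with equal totals, 410 with quantile scaling, 1087 with array weights, 419 in a fit of these groups alone and 802 with DESeq2. Without aged Tterm 1, 2, 3, 4 and 6 the count was 128, 113, 106, 141 and 742, and without young Tterm 2, 3, 4, 5 and 6 it was 123, 141, 121, 127 and 437.

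A score of the 862 peaks called within batch 4 and 5 was then read in batch 6, a test chosen only after the results were seen. In batch 4 and 5, whose libraries chose the peaks and so set them apart, the aged libraries scored 1.97 ± 0.24 (n = 5) and the young -0.69 ± 0.034 (n = 5). In batch 6 aged Tterm 6 scored 0.51 and young Tterm 6 and 7 scored 0.59 and 0.45. Of the 862 peaks 385 had the same direction in batch 6.

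**Figure D3:**
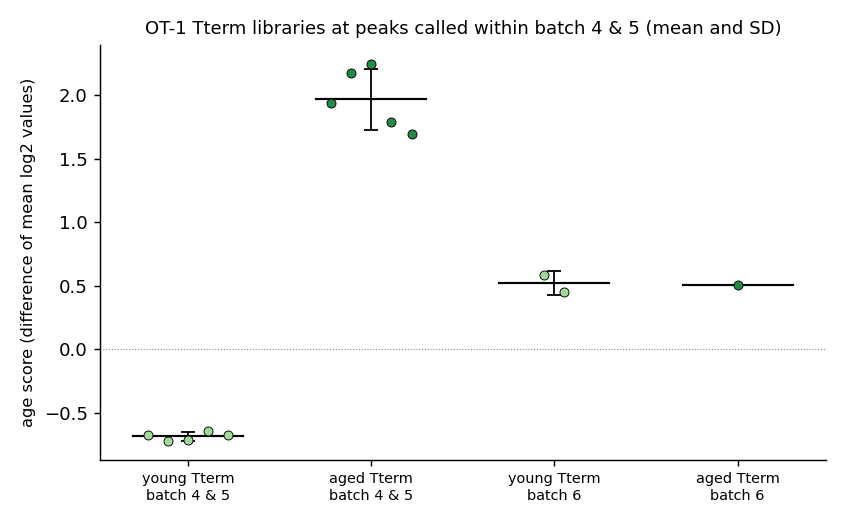
Score of the peaks called within batch 4 and 5 (vertical axis) for each OT-1 Tterm library, grouped by age and batch (horizontal axis). Each point is 1 library, with lines at the mean and bars of SD, and the means in batch 4 and 5 were 1.97 for aged and -0.69 for young.

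OT-1 Tprog, aged (n = 2, batch 6) against young (n = 2, batch 4 and 5), cannot part age from batch, and the batch term of the fit rests on Tterm. By limma 19 peaks were higher and 61 lower, with 11253 under 0.05 before adjustment, with equal totals 230 and 188 and with quantile scaling 327 and 346. Lag3, an inhibitory receptor gene, was lower (chromosome 6, 124907536 to 124908164, intragenic, 42.2 ± 8.61 against 148 ± 15.5, log2 -1.94 ± 0.37, adjusted p 0.0286). Map3k1, a kinase gene, was lower at a distal peak (chromosome 13, 111826005 to 111827489, intergenic, 139 ± 81.9 against 706 ± 17.8, log2 -2.65 ± 0.39, adjusted p 0.00763). The transcription factor gene Mef2c was lower too (chromosome 13, 83597033 to 83598260, intragenic, 42.0 ± 5.13 against 222 ± 1.37, log2 -2.61 ± 0.40). Myo10 was lower (chromosome 15, 25563388 to 25564124, intergenic, 27.6 ± 10.99 against 149 ± 8.78, log2 -2.65 ± 0.43). Kcna4, a potassium channel gene, was higher (chromosome 2, 107227898 to 107228618, intergenic, 47.7 ± 1.66 against 6.45 ± 7.55, log2 4.80 ± 0.79). Gzmb, Havcr2, Pdcd1, Tox and Tcf7 did not pass, with adjusted p 0.0759, 0.102, 0.126, 0.171 and 0.335. The effector list had a median of -0.45 (adjusted p 0.0229, estimated-correlation p 0.899), and its mean was 5.44 in aged Tprog 1 against 6.15 in aged Tprog 2 and 6.11 and 6.10 in young Tprog. The median of all peaks was -0.21, which turned to 0.06 with equal totals. The log2 levels of the aged replicates had a correlation of 0.731 across peaks, against 0.863 or more in every other pair of replicates. Counts were 131 for peaks of mean 30 or more, 418 and 673 after those scalings, 145 without a batch term, 218 with edgeR, 902 with DESeq2, 3 with a replicate block and 0 with array weights or in a fit of these groups alone. Without aged Tprog 2 the count was 17776, without aged Tprog 1 it was 227, without young Tprog 2 it was 3, without young Tterm 5 it was 47, without aged Tterm 6 it was 200 and without young Tterm 6 it was 224.

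In naive cells, aged (n = 2) against young (n = 2), both from batch 3, Gzmb was higher (chromosome 14, 56261669 to 56263049, gene end, 352 ± 22.0 against 93.1 ± 4.43, log2 1.90 ± 0.31, adjusted p 0.000525). Gzmk was also higher (chromosome 13, 113182483 to 113184098, intergenic, 226 ± 23.2 against 84.8 ± 11.001, log2 1.40 ± 0.26). Eomes, a transcription factor of memory cells, was higher (chromosome 9, 118415803 to 118417062, intergenic, 287 ± 9.60 against 89.7 ± 2.15, log2 1.67 ± 0.25). Zeb2, a factor of effector differentiation, was higher too (chromosome 2, 45018593 to 45020162, intragenic, 179.7 ± 32.2 against 21.3 ± 3.83, log2 3.01 ± 0.41). Prdm1 was higher (chromosome 10, 44537616 to 44539738, intergenic, 278 ± 1.81 against 39.6 ± 9.71, log2 2.80 ± 0.41). The chemokine gene Ccl5 was also higher (chromosome 11, 83529305 to 83529808, gene end, 61.1 ± 7.94 against 6.98 ± 2.60, log2 2.99 ± 0.47). Its relative Xcl1 was higher too (chromosome 1, 164935248 to 164936382, gene end, 328 ± 26.2 against 81.7 ± 4.67, log2 1.99 ± 0.24, adjusted p 3.17e-05). Rgs1 (chromosome 1, 144300344 to 144302123, intergenic, 290.0 ± 3.34 against 64.1 ± 1.10, log2 2.16 ± 0.31) and Itga1, which encodes the collagen receptor CD49a (chromosome 13, 115130767 to 115132298, intergenic, 131 ± 2.33 against 32.2 ± 0.982, log2 1.99 ± 0.28), were higher. Il2ra, a subunit gene of the IL-2 receptor, was higher (chromosome 2, 11692482 to 11693727, gene end, 256 ± 17.1 against 55.9 ± 6.43, log2 2.18 ± 0.34). Pdcd1 was also higher (chromosome 1, 94040457 to 94040744, intragenic, 80.2 ± 3.00 against 24.8 ± 2.19, log2 1.66 ± 0.35). Tcf7 was higher at a distal peak (chromosome 11, 52293846 to 52294978, intergenic, 225 ± 2.38 against 76.3 ± 19.4, log2 1.57 ± 0.36). Id3 was lower (chromosome 4, 136106476 to 136107365, intergenic, 12.5 ± 3.76 against 101.04 ± 14.7, log2 -2.94 ± 0.46), as was Slamf6 (chromosome 1, 171915621 to 171916508, gene end, 44.0 ± 3.09 against 126 ± 8.02, log2 -1.49 ± 0.35), and Tox and Havcr2 did not pass, with adjusted p 0.0652 and 0.0887.

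The largest differences in naive cells included Galnt14, which was higher with age (chromosome 17, 73512710 to 73514678, intragenic, 256 ± 30.5 against 11.4 ± 0.241, log2 4.37 ± 0.36, adjusted p 3.19e-07), and Tnfrsf8, which encodes CD30 (chromosome 4, 145277732 to 145278829, intragenic, 279.9 ± 35.4 against 11.9 ± 3.19, log2 4.46 ± 0.55, adjusted p 3.6e-05). Map3k8, a kinase gene of inflammatory signalling, was higher (chromosome 18, 4347701 to 4348514, intragenic, 110.4 ± 26.8 against 4.17 ± 3.17, log2 4.56 ± 1.15). Erc1 was lower (chromosome 6, 119630576 to 119631062, intragenic, 1.40 ± 0.793 against 123 ± 35.4, log2 -5.71 ± 1.45). Genes of B cells moved both ways: Blk was lower (chromosome 14, 63416542 to 63417396, gene end, 1.63 ± 2.31 against 43.4 ± 5.84, log2 -4.42 ± 0.61) and Cd22 was higher (chromosome 7, 30886763 to 30888207, intergenic, 274 ± 5.13 against 83.9 ± 13.2, log2 1.70 ± 0.27). The B cell list mean was lower in both aged libraries (4.77 or less against 4.82 or more), as was the myeloid mean (5.51 or less against 5.77 or more). By limma 3430 peaks were higher and 976 lower, with equal totals 2862 and 1437, and with quantile scaling 3372 and 1753. The median of all peaks moved from 0.11 to -0.12 with equal totals. The labels do not say whether the aged sort left out memory-like cells.

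Of the effector genes 13 had a higher peak in aged naive cells, with 48 peaks higher and 1 lower (63 and 1 adjusted over the list alone) and an adjusted p of 1.79e-13 (estimated-correlation p 0.287). Virtual memory peaks were higher in 19 cases, at Cd44, Cxcr3, Eomes and Il2rb (24 adjusted over the list alone), with an adjusted p of 5.30e-10 (estimated-correlation p 0.0691). Terminally exhausted peaks were higher in 19 cases and lower in 1 (28 and 2 adjusted over the list alone), with an adjusted p of 1.41e-05 (estimated-correlation p 0.323). Age-associated peaks were higher in 15 cases, among them peaks of Ccl5, Eomes, Gzmk and Pdcd1 (24 higher and 1 lower adjusted over the list alone), with an adjusted p of 0.00177 (estimated-correlation p 0.335). Interferon response peaks were higher in 6 cases (8 adjusted over the list alone), with an adjusted p of 0.000846 (estimated-correlation p 0.2996). Tissue residency peaks were higher in 24 cases and lower in 3 (31 and 3 adjusted over the list alone), with an adjusted p of 1.45e-05 (estimated-correlation p 0.2996). Progenitor peaks were higher in 18 cases and lower in 8, with a median of 0.01, a mean of -0.01 and, with equal totals, a median of -0.22. NK cell peaks were higher in 2 cases, at Klrb1c (6 adjusted over the list alone, adjusted p 0.00467, estimated-correlation p 0.2996). CD4 and regulatory T cell peaks were higher in 3 cases and lower in 4, with a median of -0.20 (adjusted p 0.00177, estimated-correlation p 0.2996). Array weights gave 24583 called peaks and a fit of these groups alone 26662. Without aged naive 1 and 2 the count was 1053 and 1988, and without young naive 1 and 2 it was 1371 and 1362, where a lone library was assumed to vary like the other groups.

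**Figure D4:**
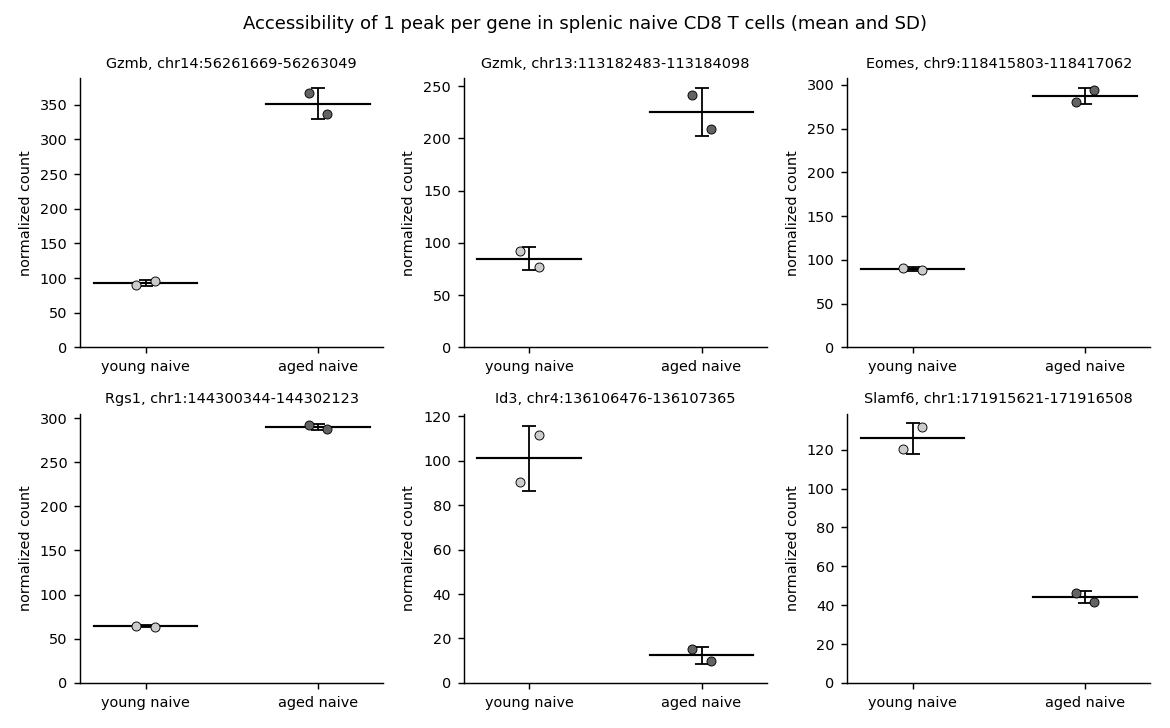
Normalized reads (vertical axis) of peaks at Gzmb, Gzmk, Eomes, Rgs1, Id3 and Slamf6 in young and aged naive cells (horizontal axis). Each point is 1 library, with lines at the mean and bars of SD, and the Gzmb mean was 352 in aged and 93.1 in young cells.

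The age differences of different cell types were compared across 64998 overlapping peak pairs, which are not independent replicates. Endogenous Tprog and naive cells had a correlation of 0.245, and 31 of the 32 peaks called in both had the same direction. For endogenous Tterm and OT-1 Tterm the correlation was 0.104, and for endogenous Tterm and naive cells it was -0.034.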

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

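The split tests were fixed beforehand, the thinning test was added later with its prediction written before its result, and all other tests of explanations in this part were chosen only after the results were seen. Libraries far from the rest of their group were found with Dixon's ratio in 265 groups of values, of which 19 stood out, against 13.25 from chance alone at about 1 in 20.

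Aged OT-1 Tterm 6 held 1.81% of its reads in 1 peak, more than its group. It was also low at Tenm4 (22.4) and high at Myo10 (69.8). Young OT-1 Tterm 6, also of batch 6, was high at Havcr2 (1469) and Adgrg3 (958) and apart at chromosome 3, 148419346 (18.9). Young OT-1 Tterm 7 of the same batch was apart in the progenitor list mean (5.597), at Atp2b4 (116), at Nav1 (79.7) and at chromosome 3, 61488730 (29.7). Aged OT-1 Tterm 3 had 89.2 at chromosome 7, 124874009 and the same value at chromosome 3, 21009240, and aged OT-1 Tterm 5 stood apart in the virtual memory list mean (5.88). Young endogenous Tterm 1 had the lowest position score of its group (2.55). Among young endogenous Tprog, library 2 was high at Rbms3 (72.6) and at Gzmk (775), library 4 was apart at Itpripl2 (15.1), library 3 was high at Havcr2 (537) and library 1 was high at H60c (18.9). The age difference was another in naive than in OT-1 Tterm cells at 1704 peaks, and another in OT-1 Tterm than in OT-1 Tprog at 12 peaks, which fell to 0 without young OT-1 Tprog 2.

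Random splits of the libraries asked whether chance can be excluded. In endogenous cells 1 of 56 splits reached the real 6 peaks of Tterm age (highest other 2). For Tprog age 1 of 35 reached 119 (highest other 3). For young Tterm against Tprog 1 of 100 reached 18376 (highest other 7993). These shares, not adjusted over the tests, do not exclude chance, and need independent libraries. For aged Tterm against Tprog 10 splits, 1 of them real (8699, highest other 0), are too few. For age by subset the test is void, since any split reaches 0 (100 of 100, highest other 21). For OT-1 Tterm age 2 of 100 splits reached the real 224. The highest other, 774, exchanged aged and young Tterm 6 within batch 6, so it says nothing of batch.

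A pattern was the chromosome 5 cluster of Gm5861 and Speer1, whose 30 tested peaks had a median of -1.04 in aged OT-1 Tterm, -0.67 in OT-1 Tprog, -0.69 in endogenous Tterm and -0.45 in endogenous Tprog. A copy-number variant of all aged animals is argued against by naive cells, where the median was 0.85. Batch 6 is argued against by -1.06 within batch 4 and 5. Within batch 6 the 1 aged Tterm library (5.92) also lay below both young ones (7.53 and 6.68), too few to settle batch 4 against 5, which stays open, as does a variant in some cohorts. Reads shared between near-identical copies could also move the peaks together, and their SD of 0.304 cannot tell.

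In aged naive cells 3430 peaks were higher. Scaling is argued against by 2862 higher peaks with equal totals, and depth by 3435 after thinning to 12.9 megareads. Memory-like cells in the aged sort might raise these peaks. The 752 of them open in young OT-1 Tterm reached a median of 45.2% of the gain there (interquartile range 30.6% to 67.6%). That cannot tell. Naive-restricted peaks chosen as lower had a median of -2.56, which would need a share of 83.1% of such cells. The young libraries may have helped choose them. All naive-restricted peaks had a median of -0.77, which a share of 41.5% would give, so this stays open.

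The 862 age peaks of OT-1 Tterm in batch 4 and 5 did not carry over to batch 6, where their signed median was -0.0878, against 1.15 in the libraries that chose them, which the choice raises. Exchanged labels of aged Tterm 6 and young Tterm 6 stay open. Their score difference was -0.0776, but no score gap by age was seen in batch 6, so it cannot tell. An age effect common to both batches could be hidden, since batch 6 holds 1 aged Tterm library. Whether age or batch 4 and 5 made the difference stays open.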

How the results depend on the processing

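Alternatives were fixed before the data were examined, except for tests named in the other parts as chosen only after the results were seen. Motif analyses, of whole peaks and of their central 200 bp, were not run. For counts that did not hold, the cause was not tested.

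For endogenous Tterm age (6 peaks) the count was 12 with equal totals, 97 with array weights, 27 in a fit of these groups alone, 27 with edgeR and 268 with DESeq2. For endogenous Tprog age (119) it was 248 with array weights and 674 with DESeq2. Tadys against Tterm gave 690 with array weights and 678 in a fit of these groups alone, and Tadys against Tprog 426 and 398. The age by subset count of 0 was 19 with DESeq2. OT-1 Tterm age (224) gave 338 at pseudocount 5, 390 with equal totals, 410 with quantile scaling, 1087 with array weights, 419 in a fit of these groups alone, 802 with DESeq2, 862 within batch 4 and 5 and 0 within batch 6, with 1 aged library. OT-1 Tprog age (80) gave 131 at a mean of 30 or more, 418 with equal totals, 673 with quantile scaling, 0 with array weights, 145 without a batch term, 0 in a fit of these groups alone, 218 with edgeR and 902 with DESeq2. OT-1 young Tterm against Tprog gave 13368 with array weights. OT-1 aged Tterm against Tprog gave 1861 with array weights, 203 in a fit of these groups alone and 1948 within batch 6. Naive age gave 24583 with array weights and 26662 in a fit of these groups alone. With estimated correlation 0 of 50 list results passed. The correlation of the endogenous age differences was 0.173 for peaks of mean 30 or more. With all libraries kept, young and aged endogenous Tterm against Tprog and OT-1 Tterm against naive held by count in every setting. With equal totals the larger side turned for all 4 comparisons of Tterm against Tprog, for OT-1 Tterm against naive and for OT-1 Tprog age.

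With the replicate number as a replicate block, endogenous Tterm age gave 0 peaks and Tprog age 43, OT-1 Tprog age 3, OT-1 young Tterm against Tprog 3766 and aged 4556. It gave 15772 for young and 8073 for aged endogenous Tterm against Tprog, 3033 and 3629 for Tadys against Tterm and Tprog, 241 for OT-1 Tterm age, 4105 for naive age and 29368 for OT-1 Tterm against naive. Only between aged OT-1 Tterm and Tprog were all same-number correlations over 0.1 (0.137 and 0.201), so a paired analysis was not preferred.

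With each library left out in turn the counts ranged from 1 to 14 for endogenous Tterm age, 15 to 186 for Tprog age, 14528 to 18379 for young and 5402 to 7777 for aged Tterm against Tprog, 1713 to 5299 for Tadys against Tterm, 1368 to 6575 for Tadys against Tprog and 0 to 1 for age by subset. They ranged from 106 to 742 for OT-1 Tterm age, 3 to 17776 for OT-1 Tprog age, 1884 to 7305 for OT-1 young and 6720 to 30254 for OT-1 aged Tterm against Tprog, 1053 to 1988 for naive age and 19496 to 19578 for OT-1 Tterm against naive. The correlation of age differences ranged from 0.0327 to 0.181, Tadys minus Tterm in the position score from -0.88 to -0.76 and Tadys minus Tprog from 0.54 to 0.67.

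The added contrast of naive against OT-1 Tterm age (1704) gave 1938 with equal totals and 2521 with quantile scaling, and 227 to 657 with 1 naive library left out. Limits are groups of 2 libraries, batch and age that coincide in OT-1 Tprog, possible technical replicates and gene assignment by distance. In simulation 2.99% (naive age) to 41.8% (OT-1 Tterm age) of 67 peaks changed 2-fold were recovered. A larger share of changed peaks was not tried, nor was group size parted from depth.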

Other observations

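Every contrast and test in this part was chosen only after the results were seen. Tadys was compared with the mean of aged Tterm and aged Tprog, which can also call peaks that lie between the other subsets. By limma 739 peaks were higher in Tadys and 2348 lower, with 15544 under 0.05 before adjustment. Tert, which encodes the telomerase reverse transcriptase, was higher (chromosome 13, 73636054 to 73636384, inside the gene, 35.8 against 4.12 ± 2.39 in Tterm and 1.95 ± 1.75 in Tprog, log2 3.39 ± 0.79). Pepd was higher (chromosome 7, 34943224 to 34943537, 43.6 against 4.93 ± 4.45 and 2.68 ± 2.42). Il6st was lower (chromosome 13, 112443264 to 112443804, 6.84 against 61.1 ± 1.62 and 96.9 ± 30.8, log2 -4.32 ± 0.56). Effector genes had 13 lower peaks, at Gzmb, Gzmk, Ifng, Klrg1, Klrk1 and Zeb2, and terminally exhausted genes 11, at Cd38, Eomes, Havcr2, Lag3, Nr4a2, Pdcd1, Prdm1 and Tigit. Progenitor genes had 10 lower peaks and 1 higher, at Id3. Tadys 1 had the lowest effector mean of the aged endogenous libraries (7.13) and the highest myeloid (7.15), melanocyte (6.38) and B cell (5.93) means, while the effector mean of Tadys 2 (7.38) lay within aged Tprog. The myeloid list had a median of 0.22 and the melanocyte list 0.17, so a share of other cells in Tadys 1 stays open for the lower peaks. Equal totals gave 956 higher and 1821 lower peaks, without Tadys 1 the count was 1034 and without Tadys 2 it was 4646.

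Aged OT-1 Tprog 1 stood apart from the other OT-1 Tprog libraries. Its log2 levels had a correlation of 0.788 with young Tprog, against 0.909 for aged Tprog 2, and their slope on the other OT-1 Tprog libraries was 0.784, against 0.937 to 0.985 for those libraries. All 15 gene lists were lowest in it, other cell types included, which says nothing of single lists. The age by subset difference of OT-1 cells, 12 peaks, was 80 without aged Tprog 1, 12239 without aged Tprog 2, 7 without young Tprog 1 and 0 without young Tprog 2. Equal totals gave 128 and quantile scaling 220.

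More memory-like cells or fewer recent thymic emigrants may lower aged naive peaks at Cd24a and Ccr9. In 99 peaks of 12 thymocyte genes, 7 with Tterm peaks of mean 30 or more, the median was -0.36 against 0.11 for all. Lower were 7 (Arpp21, Ets2, Sox4) and higher 1 (Themis). Unadjusted p was 1.56e-06 (preset correlation) and 0.00239 (estimated). Counts of T cell receptor excision circles would test emigrants.

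Age may move the same peaks in naive cells as in endogenous Tprog, for which the correlation was 0.245. A correlation as high was reached in 3 of 35 splits of the Tprog libraries (highest other 0.272), which cannot tell. More aged Tprog libraries sequenced in 1 batch with naive cells would test it.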
